A study of Mus musculus with 27 samples.

How the data were processed

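Bulk RNA sequencing was done on cells sorted from pancreatic islets or lymph nodes of 12-week-old non-obese diabetic (NOD) mice. NOD mice develop autoimmune diabetes. The transgenic animals (TG+) carry Ins2-CCL21, which places the chemokine CCL21 under an insulin promoter, and the others (TG-) do not. Per the labels, the 27 libraries fall into 8 groups: islet CD45 leukocytes (4 TG-, 4 TG+), islet gp38-high cells (2 TG-, 2 TG+), islet gp38-low cells (4 TG-, 4 TG+) and lymph node fibroblastic reticular cells, or FRCs (4 TG-, 3 TG+). FRCs are the stromal cells that form the scaffold of lymph node T cell zones. Each library's group and replicate number were taken from its label. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

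Cells were stained with antibodies, sorted into TRIzol and their total RNA purified on columns, per the labels' protocols. Libraries were made with a KAPA RNA HyperPrep kit with ribosomal RNA removal, per the labels' protocols. Reads were processed with bcl2fastq 2.17, Trim Galore 0.4.3 and STAR 2.5.2a against mm10, per the submitters' processing notes. The gene annotation release is not given in the sources used here. The authors deposited 1 table per library with raw read counts per gene in the layout of STAR's gene counter. Its first 4 lines hold reads that belong to no gene: unmapped, multimapped, outside genes, and ambiguous. In the deposited tables the first kind took 19.4% to 67.7% of the reads and the next 4.98% to 7.28%. Reads outside genes or ambiguous took 6.37% to 26.8%. These lines were left out of library sizes and tests. STAR counts only uniquely mapped reads, so genes with near-identical copies lose reads.

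The reverse-strand count column was used, because the forward-strand column held only 6.67% to 15.3% of the reads on both strands. Of 54446 gene identifiers, 54409 matched the GENCODE mouse release M21 annotation of GRCm38, the assembly that mm10 names, and took their symbols and positions from it. Ccl21a and Ccl21b have near-identical copies in this annotation and their values are uncertain. Ccl21c had no symbol match and was not analysed here. Reads assigned to genes numbered 8517844 to 25194443 per library. A count of 0 allows up to 3 counts, or 0.119 to 0.352 CPM (read counts scaled to the same total of reads in genes) over these libraries. Such floors cover counting error only, since PCR copies are not independent molecules.

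Differences between groups were tested with edgeR 4.0.16 (R 4.3.3). TMM factors, the filterByExpr filter, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at a false discovery rate of 0.05 were used. The CD45, gp38-low and lymph node FRC libraries were each fitted alone for the transgene effect. The gp38-high effect was fitted with the 12 islet stromal libraries. Each SE of a log2 difference was its absolute value divided by the square root of its F statistic. It therefore rests on the spread of all libraries in the fit, not only of the groups compared. Comparisons between populations, and differences of transgene effects, were fitted on the 19 stromal libraries with both genotypes weighted equally. The similarity of each gp38-low library to lymph node FRCs was the Pearson correlation of log2 CPM (prior count 2) across genes with the mean FRC profile. It was compared between genotypes by an exact two-sided permutation test. Gene lists of cell types and pathways, 38 in number, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists needed at least 5 measured genes. All lists are textbook markers.

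The groups, tests, gene lists and alternatives were fixed before the data were examined, except where the closing section says otherwise. The rule for named genes took 10 fixed genes (Ccl21a, Ccl21b, Ccl21c, Ccl19, Cxcl13, Pdpn, Il7, Ins1, Ins2, Ptprc). It also took up to 8 called genes in each direction with an average log2 CPM of at least 3, whose groups did not overlap. From each list described, it took the 2 to 4 members with the smallest p. Some members are not reported here, and the next was taken where fewer than 2 were left. No gene was called, so only the first and last parts of the rule named genes. Cpa1 was named for the tissue check and the genes of the expression profiles were named after their values were seen. Ccl21b did not pass the expression filter in any comparison.

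Alternatives were DESeq2 1.42.0 with its own size factors, limma-voom with sample quality weights, relative log expression size factors, no low-count filter, and the unstranded counts. Other libraries in the fit, pancreatic, immunoglobulin and mitochondrial genes left out of library sizes, the replicate number as a block, and each library left out in turn were also tried. The test was tried on simulated data with 200 changed genes, drawn from the real means and library sizes at a dispersion of 0.1. It recovered 37% of 2-fold and 99% of 4-fold changes in the CD45 comparison, 30% and 98% in gp38-low, 5% and 60% in gp38-high, and 28% and 95% in lymph node FRC. Recovery between populations was 41% and 100% for gp38-high against gp38-low, 68% and 100% for gp38-low against FRC, and 46% and 100% for gp38-high against FRC. It was 5% and 63% for the difference of transgene effects between gp38-low and FRC, and 1% and 32% for that between gp38-high and gp38-low. The real common dispersions were higher, from 0.478 in the CD45 fit to 0.766 in the fit of 19 libraries. Python 3.11.15 with scipy 1.17.1 was used for permutation tests and correlations. All 351 pairs of libraries differed by more than sampling noise, with a lowest chi-square per degree of freedom of 5.89, so no library was counted as a copy of another.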

Results

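Expression was measured in 27 libraries of sorted cells from TG- and TG+ NOD mice. Per the labels, 8 libraries held leukocytes of islet infiltrates (CD45), 4 islet gp38-high cells, 8 islet gp38-low cells and 7 lymph node FRCs. The deposited tables held 32113714 to 59605092 reads per library, and 8517844 to 25194443 of a library's reads fell in genes. Mean depth was lowest in the group labelled lymph node FRC TG+, whose 3 libraries had 8517844 to 9194044 reads in genes. The gene with the most reads was the non-coding RNA Gm26917 (ENSMUSG00000097971.3, chromosome 17, 39843013 to 39846341, mm10), which took 5.31% to 36.0% of the reads in genes. These reads counted in the CPM total, so the CPM of other genes was lowered unevenly between libraries.

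**Figure D1:**
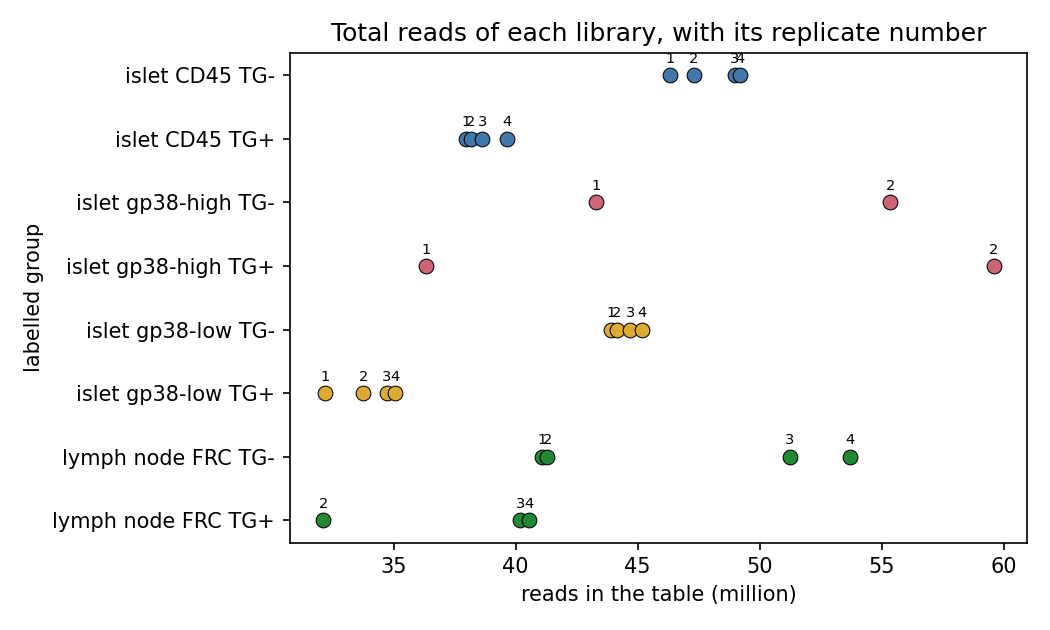
Total reads in each library's table (x axis) by labelled group (y axis), with the replicate number over each point; 1 point is 1 library. In all 8 groups the replicate numbers run in order of the read total, from 32113714 to 59605092 over all libraries.

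The genes behind the sort markers did not match the labels in 14 of 27 libraries. Ptprc (ENSMUSG00000026395.16, chromosome 1, 138062861 to 138175708) encodes CD45, the antigen common to leukocytes. Pdpn (ENSMUSG00000028583.14, chromosome 4, 143267431 to 143299564) encodes podoplanin, which is gp38. Every library held 1 of the pair far above the other, and Ptprc was the higher in 8 of 27. Among the 8 libraries labelled CD45, Pdpn was the higher in 7, and Ptprc reached 261 CPM in TG- replicate 4 against at most 5.79 CPM in the other 7. Ptprc was also the higher gene in 5 of the 7 libraries labelled lymph node FRC, among them all 3 TG+, at 169 to 633 CPM. It was the higher in 1 of 4 labelled gp38-high (TG- replicate 2, 451 CPM) and 1 of 8 labelled gp38-low (TG- replicate 1, 678.5 CPM). The mismatches fell in 7 of 14 TG- and 7 of 13 TG+ libraries. Because of these values, each library below is the library labelled with its group, and every direction refers to labels.

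**Figure D2:**
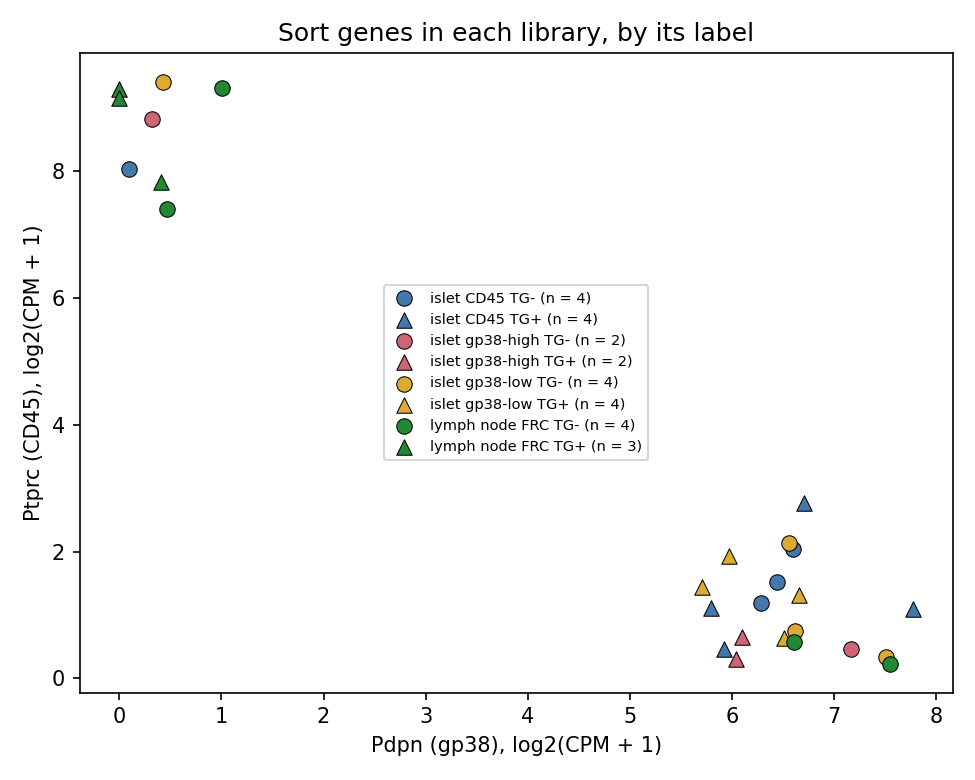
Level of Ptprc (y axis) against Pdpn (x axis) in each of the 27 libraries, both as log2(CPM + 1), with colour for the labelled population and shape for the genotype. Ptprc exceeds Pdpn in 8 libraries at the upper left, of which 1 is labelled CD45, and the other 19 sit at the lower right.

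Genes of the exocrine pancreas did not follow the labelled tissue. Cpa1 (ENSMUSG00000054446.8, chromosome 6, 30639218 to 30645363), which encodes a digestive carboxypeptidase made by acinar cells, was present at 13.2 to 500.0 CPM in all 7 libraries labelled lymph node. In 7 libraries labelled islet it was at most 0.118 CPM. Ccl21a (ENSMUSG00000094686.1, chromosome 4, 42772860 to 42773993), the lymph node form of CCL21, was at most 2.23 CPM in the 7 libraries labelled lymph node FRC. It reached 5685 CPM in the library labelled CD45 TG+ replicate 3. Correlations of log2 CPM across genes averaged 0.825 within labelled populations (83 pairs of libraries) and 0.786 between them (268 pairs). Few label permutations reached that difference (permutation test, one-sided, p = 0.0325, not adjusted for the other label tests here). Within groups of the same population and genotype the mean was 0.832 (35 pairs) and between them 0.791 (316 pairs; permutation test, one-sided, p = 0.0620). Libraries of the same genotype averaged 0.792 and those of different genotype 0.798 (permutation test, one-sided, p = 0.529). The library nearest to each one had the same population label in 7 of 27 cases.

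**Figure D3:**
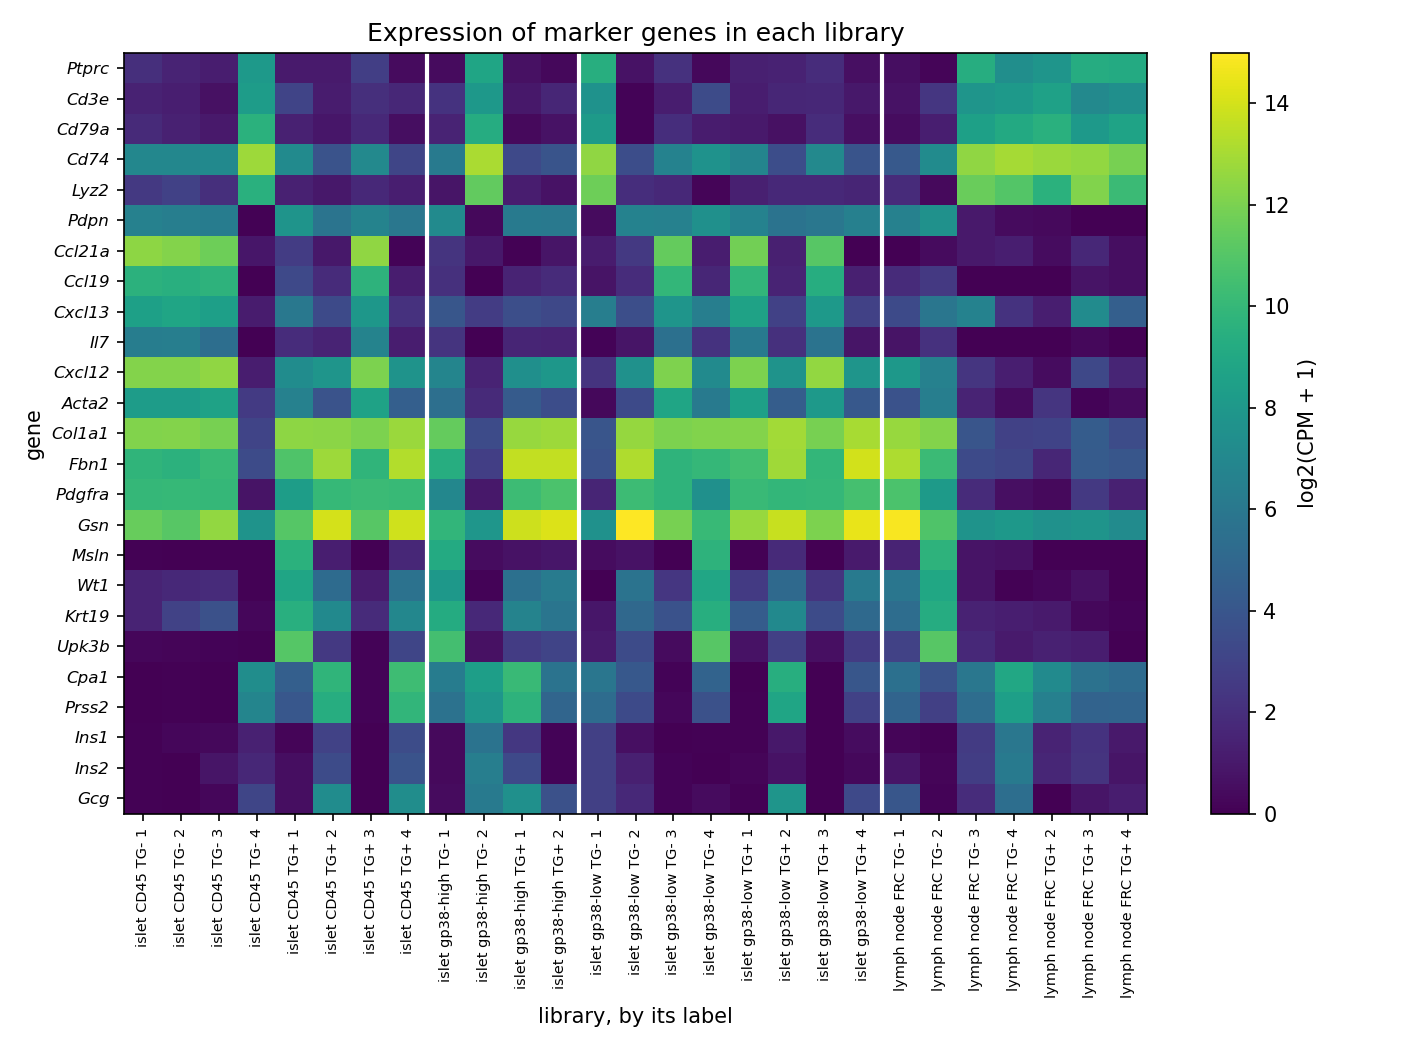
Level of marker genes (y axis) in each library (x axis, in order of its label) as log2(CPM + 1), by colour; white lines part the labelled populations. Ptprc is high in 8 libraries that come from all 4 labelled populations, and Ccl21a and Ccl19 are high in 7 libraries, none labelled gp38-high or lymph node FRC.

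At the preset correlation limma's camera called 14 of 33 gene lists for the transgene in CD45, 8 of 33 in gp38-low, 16 of 38 in gp38-high and 22 of 36 in lymph node FRC. It called 12 of 38 for gp38-high against gp38-low, 19 of 38 for gp38-low against FRC and 23 of 38 for gp38-high against FRC. For the differences of transgene effects it called 22 of 38 (gp38-low minus FRC) and 11 of 38 (gp38-high minus gp38-low). With an estimated correlation, and with fry, 0 lists were called in each of these 9 comparisons. The lists described below are a selection. Members are also given as adjusted over their list alone, which ignores the other lists and comparisons. Lists with such a call numbered 8 (CD45), 1 (gp38-low), 1 (gp38-high) and 5 (lymph node FRC) for the transgene. Between populations they numbered 1 (gp38-high against gp38-low), 24 (gp38-low against FRC) and 2 (gp38-high against FRC). For the differences of transgene effects they numbered 3 and 0. Adjusted over all genes, 0 members were called.

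The first comparison asked how islet CD45 cells differ between TG+ and TG- mice. In the libraries labelled CD45, markers of ductal epithelium were higher in TG+ for 10 of 10 members, by a median log2 difference of 5.50. They included Spp1, a secreted phosphoprotein (9.61 ± 2.25, SE, n = 4 against 4), and the keratin Krt8 (6.43 ± 1.58). Adventitial fibroblast markers were higher for 14 of 14 members (median 2.81), with the semaphorin Sema3c at 4.71 ± 1.32 and the peptidase Dpp4 at 3.25 ± 0.98. All 23 acinar genes measured were higher in the fit, among them Reg1 (4.57 ± 2.77) and Amy2b (4.47 ± 2.90), a gene whose reads can be shared with other amylase copies. Genes of MHC class II, which presents antigen to CD4 T cells, were lower for 10 of 10 members (median -5.15), such as H2-DMa (-4.55 ± 1.58) and H2-DMb2 (-7.06 ± 2.49), and T cell genes for 8 of 8 (median -5.38), such as Lck (-5.63 ± 1.92) and Trbc2 (-6.44 ± 2.49). Ptprc itself was lower by -5.44 ± 2.16. The named genes of MHC class II and T cells lay mostly in TG- replicate 4. H2-DMb2 was at 597.6 CPM there and at 0.272 to 3.66 CPM in the other 7, H2-DMa at 249.9 against at most 6.30 CPM, and Lck at 316 against at most 3.84 CPM. The ductal gene Spp1 was at 95.5 to 1899 CPM in TG+ replicates 1, 2 and 4 and at 0.709 CPM in TG+ replicate 3. The acinar signal was highest in TG+ replicates 2 and 4, with Amy2b at 617 and 731.5 CPM, against 12.8 and 0.118 CPM in TG+ replicates 1 and 3 and 42.2 CPM in TG- replicate 4.

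As sets, these lists passed limma's camera at the preset correlation, with adjusted p = 6.41e-06 (adventitial), 6.87e-06 (ductal), 7.80e-06 (acinar), 2.23e-04 (MHC class II) and 9.12e-04 (T cell). None passed with an estimated correlation (adjusted p = 0.464 for each). Without CD45 TG- replicate 4 the T cell list lost its call (adjusted p = 0.123), while the MHC class II list kept it. Adjusted over the list alone, 9 of the 10 ductal genes and 8 of the 10 MHC class II genes were called, and 0 of the others. Other lists moved too: mesothelial markers were higher for 6 of 6 members (median 6.09, adjusted p = 0.00222 by camera, 5 called when adjusted over the list alone). The mesothelial and ductal lists share the keratins Krt8, Krt18 and Krt19, so these 2 results are not separate. The mesothelial gene Msln did not pass the expression filter here. It was at 751 CPM in TG+ replicate 1 and at most 2.23 CPM in the other 7 libraries. Fibroblast matrix genes were higher for 27 of 28 (1.58e-05 by camera, 0 called over the list alone) and lymphoid chemokine and lymphotoxin genes lower for 12 of 13 (3.73e-04, 0 called). With an estimated correlation the adjusted p was 0.464 for these as well. Log2 differences of the fixed genes were -1.28 ± 2.80 (Ccl21a), -1.54 ± 2.35 (Ccl19), -1.95 ± 1.60 (Cxcl13), 0.60 ± 1.23 (Pdpn), -0.92 ± 1.84 (Il7) and 2.53 ± 1.85 (Ins2), none of them called. Over all 14871 genes, edgeR called 0, with 1402 at an unadjusted p under 0.05 and a smallest adjusted p of 0.506. DESeq2 called 685 (604 higher, 81 lower) and limma-voom with quality weights 6150 (3104 higher, 3046 lower), while without CD45 TG+ replicate 3 edgeR called 519 (395 higher, 124 lower).

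Among the libraries labelled gp38-low, cell cycle genes were lower in TG+ for 23 of 23 members, by a median log2 difference of -1.48, with the kinesin Kif20a at -1.62 ± 0.59 and the replication factor Mcm5 at -1.88 ± 0.84 (SE, n = 4 against 4). MHC class II genes were lower for 10 of 10 (median -4.51), such as its master regulator Ciita (-5.38 ± 2.10) and H2-DMb2 (-5.11 ± 2.02). Fibroblast matrix genes were higher for 26 of 28 (median 0.61), with Postn at 1.78 ± 1.09 and Lum at 1.27 ± 1.35. FRC genes were higher for 17 of 18 (median 0.61), with Il6 at 0.94 ± 1.13 and Grem1 at 1.59 ± 2.2. Ptprc, which marks leukocytes, was lower by -6.76 ± 2.57, and 678.5 CPM of it lay in TG- replicate 1 alone. That library also held H2-DMb2 at 278.5 CPM against at most 3.95 CPM in the other 7, and Mcm5 at 118 against at most 18.7 CPM.

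By limma's camera the adjusted p was 2.19e-08 for the cell cycle, 1.16e-06 for matrix, 8.63e-05 for MHC class II and 0.0226 for FRC genes, and 0.828 for all 4 with an estimated correlation. No member of these lists was called when adjusted over the list alone. Without gp38-low TG- replicate 1, the library with high Ptprc, the call was lost for the cell cycle (adjusted p = 0.0561), MHC class II (0.240) and FRC lists (0.792). With limma-voom and quality weights the cell cycle list also lost its call (adjusted p = 0.0929). The FRC call was also lost without TG- replicate 2 (0.0803), TG- replicate 4 (0.139), TG+ replicate 1 (0.177) or TG+ replicate 3 (0.324), and its direction turned under limma-voom with quality weights (adjusted p = 0.510). The lymphoid stroma genes Ccl21a (0.81 ± 2.99), Ccl19 (0.47 ± 2.53), Cxcl13 (0.65 ± 1.41), Il7 (1.10 ± 1.81) and Pdpn (-0.31 ± 1.12) differed by less than the spread between libraries. Of 14095 genes edgeR called 0, with 273 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0.

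In the libraries labelled gp38-high, 28 of 28 fibroblast matrix genes were higher in TG+ (median log2 difference 3.21), with Serpinf1, a secreted serpin, at 4.0 ± 1.66 and fibronectin, Fn1, at 3.24 ± 1.35 (SE, n = 2 against 2). T cell genes were lower for 23 of 23 and B cell genes for 19 of 20. This T cell and B cell difference lay in 1 library, TG- replicate 2. It held 353 CPM of the T cell factor Tcf7, 130.2 CPM of Cd2 and 624 CPM of the B cell receptor subunit Cd79a. TG- replicate 1 held 4.74, 0.144 and 1.87 CPM of these. Tnfrsf13c, the BAFF receptor of B cells, was at 73.6 CPM in replicate 2 and had 0 reads in both TG+ libraries. The same library was low in matrix genes such as Col1a1 (9.65 CPM, against 2755 CPM in TG- replicate 1) and Col3a1 (15.9 against 4811 CPM). Col1a1 was at 6512 and 7078 CPM in TG+. Serpinf1 was at 7.855 CPM in TG- replicate 2 and 66.1 CPM in TG- replicate 1, against 488.3 and 531.3 CPM in TG+. Fn1, unlike these, was alike in the TG- libraries (752.4 and 746.5 CPM) and at 6892 and 7384 CPM in TG+. TG- replicate 1 also held the mesothelial gene Msln at 573 CPM, against 0.693 and 0.873 CPM in TG+.

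Limma's camera gave adjusted p = 1.68e-13 for matrix, 1.60e-06 for T cell and 3.31e-05 for B cell genes, and 0.726 for all 3 with an estimated correlation. No member was called when adjusted over the list alone. Without gp38-high TG- replicate 2 the T cell and B cell lists turned to higher in TG+ (adjusted p = 0.973 and 0.741); with only the 4 gp38-high libraries in the fit the B cell list lost its call (0.111). Ptprc (-9.39 ± 4.34), Ccl21a (-2.16 ± 4.07), Ccl19 (0.72 ± 3.43), Cxcl13 (0.04 ± 1.79), Pdpn (0.17 ± 1.97), Il7 (0.29 ± 2.57), Ins1 (-3.75 ± 2.86) and Ins2 (-3.45 ± 2.79) had wide errors. Of 17937 genes edgeR called 0 (920 at an unadjusted p under 0.05, smallest adjusted p 0.663), DESeq2 31 (22 higher, 9 lower) and limma-voom 0.

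For the libraries labelled lymph node FRC, the comparison of TG+ with TG- asked whether the transgene in beta cells also shifts stroma outside the pancreas. Fibroblast matrix genes were lower in TG+ for 28 of 28 members, by a median log2 difference of -7.40, such as Fbln2 (-7.69 ± 2.56) and Col5a1 (-7.45 ± 2.53; SE, n = 3 against 4). Ductal and simple epithelial genes were lower for 10 of 10 (median -4.32), such as the keratins Krt18 (-5.11 ± 1.62) and Krt19 (-7.95 ± 2.71). T cell genes were higher for 23 of 23 (median 1.13), with Themis at 1.39 ± 1.86 and Cd28 at 1.08 ± 1.5. Pdpn, the gp38 gene, was at 0 to 0.326 CPM in the 3 TG+ libraries and at 0.378 to 186.7 CPM in the 4 TG- libraries. Ptprc was high in all 3 TG+ libraries and in TG- replicates 3 and 4 (633 and 169 CPM). Fbln2 lay at 1210.0 and 852 CPM in TG- replicates 1 and 2 and at most at 5.28 CPM in the other 5 libraries. Krt18 lay at 113.9 and 165.0 CPM in TG- replicates 1 and 2, and Krt19 at 39.6 and 629.9 CPM. In the other 5 these keratins were at most 4.35 and 1.71 CPM. TG- replicate 2 also held the mesothelial gene Msln at 821.3 CPM, against 1.77 CPM in TG- replicate 1.

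Adjusted p by limma's camera was 2.44e-09 for matrix, 4.48e-06 for ductal and 4.17e-08 for T cell genes, and 0.496 for each with an estimated correlation. Adjusted over the list alone, 26 of the 28 matrix genes and 6 of the 10 ductal genes were called, and 0 T cell genes. Ptprc (1.39 ± 2.07), Ccl21a (0.64 ± 1.20), Cxcl13 (0.57 ± 1.44), Ins1 (-2.94 ± 2.14) and Ins2 (-3.19 ± 1.99) were not called. Over 13819 genes edgeR called 0, with 981 at an unadjusted p under 0.05 and a smallest adjusted p of 0.696, limma-voom 0, and DESeq2 924 (2 higher, 922 lower).

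Against gp38-low libraries, those labelled gp38-high held more of the acinar genes, for 25 of 25 members (median log2 difference 2.43). The trypsin inhibitor Spink1 was at 2.60 ± 1.40 and the protease Ctrl at 2.49 ± 1.37 (SE, n = 4 against 8). Ctrl was highest in gp38-high TG+ replicate 1 (547.1 CPM), against 20.7 to 152.3 CPM in the other gp38-high libraries. It reached 317.9 CPM in gp38-low TG+ replicate 2. Beta cell genes were higher for 14 of 17 (median 1.08), with the insulin genes Ins2 at 4.18 ± 1.61 and Ins1 at 3.26 ± 1.63. Insulin was highest in gp38-high TG- replicate 2 (Ins2 82.4 CPM), against 0.119 to 8.94 CPM in the other 3 gp38-high libraries. FRC genes were lower for 18 of 18 (median -2.64), such as Ch25h (-2.71 ± 0.91) and Bst1 (-7.49 ± 2.65). Pericyte and smooth muscle genes were lower for 17 of 17 (median -2.67), such as Notch3 (-4.35 ± 1.70) and Tagln (-4.25 ± 1.66). Bst1 lay at 236.6 CPM in gp38-low TG- replicate 3 and at 354.4 and 201.1 CPM in TG+ replicates 1 and 3. In the other gp38-low libraries it was at most 15.0 CPM. Tagln lay at 247.8 to 446.3 CPM in the same libraries, against at most 13.4 CPM in the others and 16.7 CPM in gp38-high. Notch3, Ch25h, Ccl21a and Ccl19 were also highest there. Pdpn, which the sort should separate, differed by -0.61 ± 1.41, at 68.9 ± 58.4 CPM in gp38-high (SD, n = 4) and 84.4 ± 51.7 CPM in gp38-low (SD, n = 8).

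The set test (limma's camera) gave adjusted p = 3.62e-25 for acinar, 4.35e-10 for FRC, 6.49e-05 for pericyte and 1.00e-04 for beta cell genes. With an estimated correlation the adjusted p was 0.425 for acinar and FRC, 0.495 for pericyte and 0.441 for beta cell genes. With members adjusted over the list alone 0 were called, and without gp38-high TG- replicate 2 the pericyte (adjusted p = 0.0848) and beta cell (0.0967) lists lost their calls. The chemokine genes Ccl21a (-10.31 ± 3.38), Ccl19 (-7.81 ± 2.88) and Cxcl13 (-4.01 ± 1.48), as well as Il7 (-3.82 ± 1.87) and Ptprc (-0.85 ± 1.98), had an adjusted p of 1.0 in edgeR. EdgeR called 0 of 18396 genes (509 at an unadjusted p under 0.05), limma-voom 0, and DESeq2 141 (5 higher, 136 lower).

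Relative to the libraries labelled lymph node FRC, those labelled gp38-low held more of the FRC genes themselves: 18 of 18 members were higher (median log2 difference 4.50), with Il6 at 4.38 ± 1.03 (SE, n = 8 against 7). Grem1, a BMP antagonist made by FRCs, was at 67.5 ± 102 CPM (SD, n = 8) in gp38-low and at most 2.05 CPM in FRC libraries. In the fit Ccl21a (10.18 ± 2.72) and Ccl19 (8.65 ± 2.43), the T zone chemokines, and Il7 (6.18 ± 1.79) were higher too, though not called. Cxcl13 was at 1.45 ± 1.04 and Pdpn at 4.79 ± 1.52. Ccl21a lay at 2809 CPM in gp38-low TG- replicate 3 and at 3582 and 2162 CPM in TG+ replicates 1 and 3. In the other gp38-low libraries it was at most 4.69 CPM, against at most 2.23 CPM in FRC libraries. Ccl19, Il7 and Grem1 were highest in the same gp38-low libraries, with at most 2.68, 3.63 and 10.4 CPM in the others. Matrix genes were higher for 27 of 28 (median 4.31), such as Bgn (5.03 ± 1.41) and Fn1 (2.51 ± 0.75). T cell genes were lower for 23 of 23 (median -4.69), such as Tcf7 (-4.11 ± 1.29) and Cd2 (-5.48 ± 1.74), and B cell genes for 19 of 20, such as Cd79a (-5.36 ± 1.73). Vpreb3, another B cell gene, was at 8.88 ± 6.87 CPM (SD, n = 7) in FRC libraries and 1.28 ± 3.53 CPM (SD, n = 8) in gp38-low.

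The named T cell and B cell genes ran with Ptprc, which was lower by -4.37 ± 1.78. The chemokine difference did not run with it. FRC TG- replicates 1 and 2 held Ptprc at 0.494 and 0.175 CPM, but Ccl21a at 0 and 0.350 CPM. Ins1 (-3.20 ± 1.51) and Ins2 (-3.42 ± 1.48) were also lower in the libraries labelled islet. The insulin difference lay mostly in FRC TG- replicate 4 (Ins1 59.3 and Ins2 71.1 CPM), while the other 6 FRC libraries held at most 5.13 and 5.60 CPM and gp38-low at most 6.09 and 6.18 CPM. Adjusted p by limma's camera was 6.41e-06 for FRC, 5.27e-09 for matrix, 3.98e-09 for T cell and 1.76e-07 for B cell genes, and 0.481 for each with an estimated correlation. Calls among members, adjusted over the list alone, numbered 17 FRC, 27 matrix, 20 T cell and 17 B cell genes. Over 18396 genes edgeR called 0, with 6639 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0943. DESeq2 called 4718 (2916 higher, 1802 lower) and limma-voom with quality weights 8632 (4597 higher, 4035 lower). Without gp38-low TG- replicate 1, edgeR called 5403 (2809 higher, 2594 lower), and without lymph node FRC TG- replicate 1 it called 1369 (1021 higher, 348 lower).

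Libraries labelled gp38-high also differed from those labelled lymph node FRC in epithelial genes, which were higher for 13 of 13 ductal members (median log2 difference 4.34), such as Sox9 (5.65 ± 1.53) and Muc1 (3.89 ± 1.17; SE, n = 4 against 7). Sox9 lay at 0.6185 CPM in gp38-high TG- replicate 2 and at 94.98 to 226.6 CPM in the other gp38-high libraries. It lay at 42.24 and 21.84 CPM in FRC TG- replicates 1 and 2 and at most 0.777 CPM in the other FRC libraries. Muc1 was at 3.711 against 52.51 to 204.2 CPM in these gp38-high libraries. In FRC it was at 22.04 and 22.19 against at most 2.486 CPM. Both genes were thus low in the libraries of either label with high Ptprc. T cell genes were lower for 23 of 23 and B cell genes for 19 of 20. Cd2 averaged 81.8 ± 61.1 CPM in FRC libraries (SD, n = 7) and 32.6 ± 65.1 CPM in gp38-high (SD, n = 4), and Trac, the T cell receptor alpha constant gene, 100.8 ± 76.5 and 41.6 ± 83.1 CPM. Cr2 averaged 55.9 ± 41.3 CPM in FRC libraries and 24.1 ± 47.5 CPM in gp38-high, and Cd79b 249.6 ± 189 and 94.6 ± 189 CPM. The gp38-high values lay in TG- replicate 2, with Cd2 at 130.2, Trac at 166.3, Cr2 at 95.4 and Cd79b at 378.1 CPM. The other gp38-high libraries held at most 0.861 CPM of Cr2 and 0.1435 CPM of each of the rest. Pdpn was higher by 4.19 ± 1.58 and Ptprc lower by -5.22 ± 2.53.

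Adjusted p by limma's camera was 2.24e-05 for ductal, 4.08e-09 for T cell and 1.04e-07 for B cell genes, and 0.383 for each with an estimated correlation. Adjusted over the list alone, 12 of 13 ductal genes were called and 0 of the others. Ccl21a (-0.12 ± 2.08), Ccl19 (0.84 ± 2.01), Cxcl13 (-2.56 ± 1.38), Il7 (2.36 ± 1.74), Ins1 (0.06 ± 1.71) and Ins2 (0.76 ± 1.60) had adjusted p of 0.289 or more in the edgeR fit. EdgeR called 0 of 18396 genes (3014 at an unadjusted p under 0.05, smallest adjusted p 0.290), limma-voom 0 and DESeq2 711 (328 higher, 383 lower).

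The transgene effect in gp38-low was set against that in lymph node FRC libraries as a difference of differences. Matrix genes had the higher effect in gp38-low for 28 of 28 members (median log2 difference 7.85), such as Col14a1 (7.40 ± 2.44) and Col5a2 (8.60 ± 2.87; SE, n = 8 and 7). T cell genes had the lower effect for 23 of 23, with Cd2 at -8.48 ± 3.31; Ubash3a had 0 reads in the 4 gp38-low TG+ libraries and 24.3 ± 9.86 CPM in the FRC TG+ libraries (SD, n = 3). Pdpn (8.55 ± 2.98) and Ptprc (-8.00 ± 3.50) went with them. Col14a1 lay at 4.89 to 16.9 CPM in the FRC TG+ libraries, all with high Ptprc. In FRC TG- libraries it lay at 3382 and 1217 CPM in replicates 1 and 2. In FRC TG- replicates 3 and 4, which hold high Ptprc, it lay at 15.4 and 15.7 CPM. It was at 19.6 CPM in gp38-low TG- replicate 1, also with high Ptprc, and at least 574 CPM in the other gp38-low libraries. The difference thus followed which labelled libraries held high Ptprc. The camera test of limma gave adjusted p = 8.91e-09 for matrix and 2.37e-09 for T cell genes, and 0.441 for both with an estimated correlation. Adjusted over the list alone, 27 matrix genes were called and 0 T cell genes. Ccl21a (0.27 ± 3.59), Ccl19 (2.38 ± 3.48), Cxcl13 (0.14 ± 2.02), Il7 (4.39 ± 3.15), Ins1 (0.80 ± 3.01) and Ins2 (0.45 ± 3.08) were not called. EdgeR called 0 of 18396 genes (2454 at an unadjusted p under 0.05, smallest adjusted p 0.369), limma-voom 0 and DESeq2 587 (467 higher, 120 lower).

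Between the islet sorts, the transgene effect on matrix genes was higher in gp38-high than in gp38-low for 28 of 28 members (median log2 difference 2.60), with Fn1 at 2.75 ± 1.67 and Serpinf1 at 3.72 ± 2.30 (SE, n = 4 and 8). B cell genes had the lower effect in gp38-high for 19 of 20, with Spib at -6.87 ± 3.44; Cr2 was at 0.861 and 95.4 CPM in the TG- libraries of gp38-high and at most 0.126 CPM in the TG+ libraries. Limma's camera gave adjusted p = 1.32e-09 for matrix and 7.66e-04 for B cell genes, and 0.966 for both with an estimated correlation. Adjusted over the list alone, 0 members were called. Without gp38-high TG- replicate 2, the library with 451 CPM of Ptprc, the matrix list lost its call (adjusted p = 0.258) and the B cell list turned to higher (0.0330), and without gp38-low TG- replicate 4 the B cell call was lost (0.102). Ccl21a (-2.91 ± 4.16), Ccl19 (0.32 ± 3.78), Cxcl13 (-0.56 ± 2.38), Pdpn (0.54 ± 2.75), Il7 (-0.74 ± 3.08), Ins1 (-1.38 ± 3.45), Ins2 (-0.47 ± 3.55) and Ptprc (-2.60 ± 3.91) differed by less than the spread. EdgeR called 0 of 18396 genes (36 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 61 (2 higher, 59 lower).

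Whether gp38-low libraries lie nearer to lymph node FRCs in transgenic mice was asked of whole profiles. The correlation with the mean lymph node FRC profile was 0.777 ± 0.126 in TG- and 0.710 ± 0.0144 in TG+ libraries (SD, n = 4 each), a difference of -0.0665 within the spread (exact permutation test, two-sided, p = 0.371 over 70 splits). In the library labelled gp38-low TG- replicate 1, which holds the leukocyte gene Ptprc, the correlation was 0.964, and in the other 7 it lay between 0.695 and 0.736. Without that library the difference was -0.0040 (exact permutation test, p = 0.714). The reference holds 5 libraries in which Ptprc exceeds Pdpn.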

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

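The tests in this part were chosen after the results were seen, except limma-voom with quality weights, which was planned. Values that stood apart from the other 3 libraries of their labelled group numbered 22 of 75 sets, where chance gives about 3.8. In the library labelled CD45 TG- replicate 4 these were Ptprc (261 CPM, the CD45 gene), Cpa1 (159 CPM), Ins1 (1.56 CPM), Ccl19 (0 CPM), acinar genes (0.204% of reads) and immunoglobulin genes (1.26%). In CD45 TG+ replicate 3 they were Ptprc (5.79 CPM), Ccl21a (5685 CPM), Ccl19 (808 CPM) and Il7 (104 CPM). In gp38-low TG- replicate 1 they were Ptprc (678.5 CPM), Ins1 (6.09 CPM) and immunoglobulin genes (1.73%), and in gp38-low TG- replicate 3 Ccl21a (2809 CPM), Ccl19 (984.5 CPM) and Il7 (45.9 CPM). In gp38-low TG+ replicate 2 they were Cpa1 (673 CPM) and acinar genes (0.917%). In lymph node FRC TG- replicate 4 they were Ins1 (59.3 CPM), Ins2 (71.1 CPM), Cpa1 (500.0 CPM) and acinar genes (0.619%). The forward-strand column, which no comparison uses, held from 6.67% of the reads on both strands in lymph node FRC TG- replicate 2 to 15.3% in lymph node FRC TG+ replicate 4.

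The sort genes Ptprc and Pdpn went against the labels in 14 of 27 libraries, and pancreatic genes did not follow the labelled tissue, also in some of the other 13. Mixing of CD45 and gp38 cells is argued against, since the higher of Ptprc and Pdpn exceeded the other by at least 17.9-fold in each of the 14. That ratio cannot judge carry-over of acinar or endocrine RNA into a sort, which was not tested. The transgene cannot be judged either. Of the 14, 7 are labelled TG-, but that count rests on labels that are themselves in doubt. A candidate explanation is that labels were attached to the tables in order of their read totals. In 8 of 8 groups the replicate numbers run in order of total reads, where the chance of that is 5.23e-09, and sorting all libraries by total gives 12 runs of 1 label against a permuted median of 25 (permutation p = 1e-05, the smallest that 100000 permutations can give), while the numbers follow other measures, such as reads in genes or the unmapped share, in only 1 or 2 groups. Asked for 4 clusters, the libraries also part into sizes of 8, 7, 8 and 4, which equal the numbers labelled CD45, lymph node FRC, gp38-low and gp38-high. The tables do not tell which sample each library was, so no label was changed, and any biological difference between the groups stays untested.

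limma-voom with quality weights called 6150 genes for the transgene in CD45 libraries and 8632 for gp38-low against lymph node FRC, where edgeR called 0. Without the weights voom called 0 genes in the first and 0 in the second, so the calls may come from the sample quality weights. In the CD45 fit the weight was 0.0483 for TG- replicate 4, the library with high Ptprc, and 0.258 for TG+ replicate 3, against 5.11 for TG- replicate 1.

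Other splits of the same libraries cannot test an edgeR count of 0, since every split reaches it, so they say nothing about chance. That held for 35 of 35 splits in CD45, of which 1 called any gene (highest other 1039), 35 of 35 in gp38-low (2 with calls, highest 535) and 35 of 35 in lymph node FRC (0 with calls, highest 0). Between stromal populations it held for 100 of 100 drawn splits each, in gp38-high against gp38-low (2 with calls, highest 107), gp38-low against FRC (4, highest 7563), gp38-high against FRC (3, highest 9665) and the difference of transgene effects between gp38-low and FRC (5, highest 6763). Since a few splits call up to 9665 genes where the labels call 0, some other groupings of these libraries part more genes than the labels do; what those groupings share was not tested. The transgene effect in gp38-high, with 2 libraries per genotype, and its difference from that in gp38-low were not split.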

How the results depend on the processing

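The alternatives were planned except limma-voom without quality weights and the fits without libraries whose Ptprc exceeds Pdpn, which were chosen after the result was seen. Counts of called genes were 0 in all 9 comparisons with edgeR and remained 0 with relative log expression factors, without the low-count filter, with unstranded counts, with other libraries in the fit, and with pancreatic, immunoglobulin and mitochondrial genes left out of library sizes. Without the libraries whose Ptprc exceeds Pdpn, tried in 4 comparisons (transgene in gp38-low and in gp38-high, and gp38-high against and minus gp38-low), they were also 0. DESeq2 called 685 genes (transgene in CD45), 31 (gp38-high), 924 (lymph node FRC), 141 (gp38-high against gp38-low), 4718 (gp38-low against FRC), 711 (gp38-high against FRC), 587 and 61 (differences of transgene effects, gp38-low minus FRC and gp38-high minus gp38-low), and 0 in gp38-low. limma-voom with quality weights called 6150 (CD45) and 8632 (gp38-low against FRC), and 0 elsewhere. The cause was not tested beyond the quality weights. Leaving out each library in turn gave 0 to 519 genes in CD45 (519 without TG+ replicate 3) and 0 to 5403 for gp38-low against FRC (5403 without gp38-low TG- replicate 1, 1369 without lymph node FRC TG- replicate 1), and 0 in the other 7.

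With the replicate number as a block, 0 genes were called in each comparison, so the block changed no call. Of 27 same-numbered pairs 5 had a correlation of deviations over 0.1 (range -0.913 to 0.712). The deviations are from means of labelled groups that mostly mix unlike libraries, so they cannot tell whether the numbers pair the samples. The similarity of gp38-low libraries to FRCs had the same sign throughout, from -0.0979 to -0.0040 over libraries left out. It shrank from -0.0665 to -0.0166 with only TG- lymph node libraries as the reference (exact permutation p = 0.457), and with the block an exact sign-flip p of 0.500.

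Coding lists as 1 where higher and -1 where lower, 5 list results reversed. FRC genes turned from 1 to -1 in the gp38-low transgene effect with limma-voom (adjusted p = 0.510). In gp38-high the T cell list turned from -1 to 1 without TG- replicate 2 (0.973), and the B cell list likewise (0.741) and without libraries whose Ptprc exceeds Pdpn (0.678). For gp38-high minus gp38-low the B cell list turned from -1 to 1 without gp38-high TG- replicate 2 (0.0330). The described lists otherwise kept their sign, but lost their calls in 33 cases with an estimated correlation, 33 with fry, 1 (cell cycle in gp38-low) with limma-voom, 1 with only the 4 gp38-high libraries, 6 without libraries whose Ptprc exceeds Pdpn, and 12 with 1 library left out. Named genes gained a call in 41 cases with DESeq2, 25 with limma-voom, and 24 with 1 library left out. They turned direction without a call in 37 cases under other settings and 65 with 1 library left out. Libraries of 8517844 to 25194443 reads in genes limit detection to levels above 0.119 to 0.352 CPM.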

Other observations

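The clusters, gene ranges and correlations in this part were chosen after the data were seen. By correlation of log2 CPM the 27 libraries fell into 4 clusters of 8, 7, 8 and 4 libraries, with correlations of 0.933 to 0.989 inside clusters and 0.590 to 0.937 between them. Each cluster mixes labels, with 4, 2, 4 and 4 labelled populations, so the values are ranges over libraries and not results for a group of the study. The number of clusters was set to 4, and their sizes equal the numbers of libraries labelled CD45 (8), lymph node FRC (7), gp38-low (8) and gp38-high (4); no library was assigned to another label. The first cluster held leukocyte genes: Ptprc at 169 to 678.5 CPM, the B cell genes Cd79a (267 to 754) and Ighm (2562 to 8625), the T cell gene Cd3e (132.0 to 379), the macrophage gene C1qa (193 to 1347) and Cd74, the MHC class II invariant chain (3931 to 8734). It also held acinar Cpa1 at 36.8 to 500.0 CPM. The non-coding RNA Gm26917 took 20.8% to 36.0% of its reads in genes, and 9.78% to 22.2% in the second cluster. The second cluster held the chemokines of lymphoid stroma, Ccl21a (2162 to 5685 CPM), Ccl19 (636 to 984.5), Cxcl12 (4173 to 6042) and Cxcl13 (228 to 448), with Grem1 (116 to 357) and Acta2 (275 to 456). All 7 of its libraries had Cpa1 at or under 0.118 CPM and Ins1 at or under 0.255 CPM, although all are labelled islet. Spib, a transcription factor known from B cells, lay at 182.5 to 246 CPM in this cluster, with Ighm at 3.92 to 16 CPM, and at 114 to 349 CPM in the first.

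In the third cluster matrix and adventitial fibroblast genes led, with Gsn at 13520 to 32470 CPM, Fbn1 at 6978 to 16200, Col3a1 at 10990 to 17880 and Pi16, a marker of adventitial fibroblasts, at 689 to 2318. Its Pdpn lay at 51.1 to 97.3 CPM, and pancreatic genes reached 1309 CPM for Cpa1 and 224.5 CPM for Gcg, the glucagon gene of alpha cells. The fourth cluster of 4 libraries held mesothelial genes, which mark the lining of body cavities: Msln (573 to 830 CPM), Upk3b (1461 to 2177), Muc16 (1447 to 2560), Wt1 (253 to 480) and Krt19 (586 to 702). Its Pdpn, at 143 to 218 CPM, was above that of every library in the other 3 clusters, and Igfbp5 lay at 10660 to 17760 CPM. Msln was at most 2.52 CPM in the other 3 clusters.

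Within clusters of at least 6 libraries, 6 relations between list levels were computed. In the leukocyte cluster B cell and macrophage levels ran in opposite directions (n = 8, Pearson r = -0.900, exact permutation p = 0.00231, Benjamini-Hochberg 0.0138; Spearman rho = -0.929, exact permutation p = 0.00223). Without the 2 libraries farthest from the median r was -0.824 (exact permutation p = 0.0375). B cell and T cell levels rose together there (r = 0.854, exact permutation p = 0.00523, Benjamini-Hochberg 0.0157; rho = 0.833, exact permutation p = 0.0154), but rested on 2 libraries, without which r was 0.654 (exact permutation p = 0.169). Acinar and other endocrine levels in the third cluster gave r = 0.953 (exact permutation p = 0.0193, Benjamini-Hochberg 0.0385; rho = 0.619, exact permutation p = 0.115), and 0.944 without 2 libraries (exact permutation p = 0.0639). Acinar against B cell levels in the leukocyte cluster gave r = 0.630 (Benjamini-Hochberg 0.147, exact permutation; rho = 0.643). FRC against pericyte levels in the second cluster gave r = -0.384 (Benjamini-Hochberg 0.490, exact permutation; rho = -0.393), and adventitial against FRC levels in the third r = -0.207 (Benjamini-Hochberg 0.618, exact permutation; rho = -0.119).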
